A study of Mus musculus with 24 samples.

How the data were processed

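Total RNA of 24 samples of the mouse macrophage cell line J774A.1 was labelled with biotin and hybridized to 1 array per sample, per the labels' protocols. The 8 groups of 3 samples were made from the sample titles (untreated, ethanol mock, EPA and ceramide, each uninfected and infected), and the doses, times and 10 bacteria per macrophage are those of the submitters' design text. The unit signs of the doses are garbled in the sample labels and were read from that text. Nothing in the sources says whether the 3 samples of a group were separate cultures.

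The deposited values of each array were intensity values on a linear scale, already background subtracted, since 0.344 to 0.930 percent of them are below 0, and not normalized between arrays (medians from 89.8 to 135.1). The scanner, the background method and the meaning of the call letters P, A, M and U beside each value are not given in the sources used here. Values with P had a median of 319.7, with A of 20.5 and with M of 326.7, and the highest M value was 48710 against 28640 for P. P and M were taken as above background and A as not, and "above background" in the text means P or M. What sets M apart from P is not shown by the values. U was taken as unusable. The series table of the authors also holds intensity values, quantile normalized across the 24 arrays as deposited, with a median of 107 in each column. It equalled a quantile normalization of the array files (largest difference 5.43e-08 percent for signals over 100), so it serves as no separate alternative.

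The array files were used. Values with U were set to missing, arrays were quantile normalized with limma 3.58.1 in R 4.3.3, and values under 16 were raised to 16 before taking log2. The plan named normexp background correction, which was not applied because the values were already background subtracted. A probe was tested where its letter was P or M on at least 3 of the 24 arrays, which held for 24828 of 34937 probes, and a comparison left out probes with a missing group. Names came from the deposited annotation. On the array 21590 probes had 1 gene symbol, 681 had several and 12666 had none, and the 16111 tested probes with 1 symbol covered 13928 genes. For gene lists and named genes the brightest tested probe of a gene was used. No coordinates are given, since no genome build is named.

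Group means were fitted for all 24 arrays with limma (16 residual degrees of freedom, empirical Bayes with 2.63 prior degrees of freedom), and p was adjusted within each comparison by Benjamini and Hochberg. A probe passed at an adjusted p of 0.05 with no minimum fold. Errors of differences are standard errors of the fit, errors of levels are SDs of 3 arrays, and intervals are 95 percent intervals. The comparisons were infection in each treatment and averaged over the 4, ethanol against untreated, EPA and ceramide against ethanol and against each other in each state, and the 4 interactions. These comparisons, the tests, the gene lists, the rule for named genes and the alternatives were fixed in the plan. A fold is given as "at least" where 1 group was above background on 0 of its 3 arrays, taking for each of those arrays the higher of the gene's own signal and the lowest signal with P.

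Named genes were, per comparison, the 8 largest rises and 8 largest falls that passed with no overlap of the 2 groups, up to 3 passing members of each list (or 2 with the smallest p where none passed), and Tnf, Il1b, Il6, Il10, Cxcl2, Ptgs2, Nos2, Nfkbia, Egr1, Ifnb1, Plin2 and Abca1 in any case. Further list members and the genes of the lot pattern were picked after their values were seen. The 33 lists were written from general knowledge and cover inflammation, stress, lipid metabolism, phagocytic functions, housekeeping and markers of macrophages and of 8 other cell types. They were tested with limma camera at a preset correlation of 0.01, and again with the correlation estimated for each list.

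Sets of arrays, called array lots here, were read from the U letters after the first fits. Of 210 probes with U on 6 to 23 arrays, 209 had it on whole sets of arrays, which gives lot A (untreated and ethanol, uninfected, 6 arrays), lot B (EPA and ceramide uninfected with untreated and ethanol infected, 12 arrays) and lot C (EPA and ceramide infected, 6 arrays). The labels name no lots, and what the sets stand for is not known. A lot term could not be fitted beside the groups, so comparisons within a lot and between lot steps were added. Alternatives were median scaling, an added offset of 50, no filter and a stricter filter on dim probes, trended and robust variances, array weights, a replicate block, the groups compared alone, each array left out and, for lists, the mean over a gene's probes. Added later were a floor of 32 and leaving out the 2 arrays with the highest 75th percentile of signal.

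The fit was tested on simulated data of 24334 probes, 200 of them changed. For infection averaged over treatments 98.5 percent of 2-fold changes were recovered, for infection in untreated cells 68.7 percent, for EPA against ethanol in infected cells 71.6 percent, for EPA against ceramide averaged over both states 91.0 percent and for the EPA interaction 55.2 percent. At 1.5-fold the shares were 68.7, 34.3, 32.8, 58.2 and 10.5 percent in the same order. The simulated noise was independent between probes, equal across arrays and without lots, so recovery on the real arrays may differ from these shares. The precision of all values is limited by the number of arrays, 3 per group. Arrays of 1 group correlated at 0.971 to 0.989. Probes with no symbol or several symbols were counted and not named. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.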

Results

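Messenger RNA of J774A.1 cells, a mouse macrophage line, was measured on 24 single-colour arrays of 34937 probes. The 8 groups of 3 arrays were untreated cells and cells given ethanol (the vehicle), EPA or ceramide for 3 h, each without and with a further 1 h of infection by *Mycobacterium smegmatis*, a fast-growing species that does not cause disease in healthy hosts. EPA (eicosapentaenoic acid) is described by the submitters as anti-inflammatory and ceramide as pro-inflammatory, and the comparisons ask how infection, each lipid and their combination change gene expression. Each array detected 60.3 to 66.9 percent of its probes above background, and the 3 arrays per group limit the precision of each comparison.

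After 1 h of infection, J774A.1 macrophages carried far more message for inflammatory mediators than uninfected cells. Averaged over the 4 treatments (12 infected and 12 uninfected arrays), the neutrophil-recruiting chemokine Cxcl2 rose 18.4-fold (log2 difference 4.20, standard error 0.09, adjusted p = 2.29e-16 in limma). The cytokine Tnf rose 8.16-fold (log2 difference 3.03, standard error 0.07). Ptgs2, which makes the enzyme that starts prostaglandin synthesis, rose 6.63-fold, and Il6 rose 4.86-fold. Nfkbiz, an atypical nuclear inhibitor of NF-kB that many late cytokine genes need, rose by 3.80 log2 units in untreated cells (adjusted p = 4.09e-08), where all 6 arrays were above background, and no averaged fold is given because 0 of 3 uninfected EPA arrays were. Nfkbia, the inhibitor of NF-kB that NF-kB itself induces, rose 1.78-fold from an already high level (adjusted p = 4.01e-09). Il1b was above background on all 12 infected arrays and on 0 of the 12 uninfected ones, and its rise was at least 4.70-fold in untreated cells. Nos2, the inducible nitric oxide synthase, did not pass (log2 difference 0.12, adjusted p = 0.155), and neither did Il10 (0.30, adjusted p = 0.0502) or the lipid droplet coat gene Plin2 (-0.04, adjusted p = 0.742). Of 24706 probes tested with limma, 9907 passed at an adjusted p of 0.05, against 1235 expected at an unadjusted p under 0.05, where 11894 were found. Among the 9907, 4592 were higher and 5315 lower with infection, and 248 were higher and 84 lower by 2-fold or more. With median scaling in place of quantile normalization 6382 were higher and 2829 lower.

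**Figure D1:**
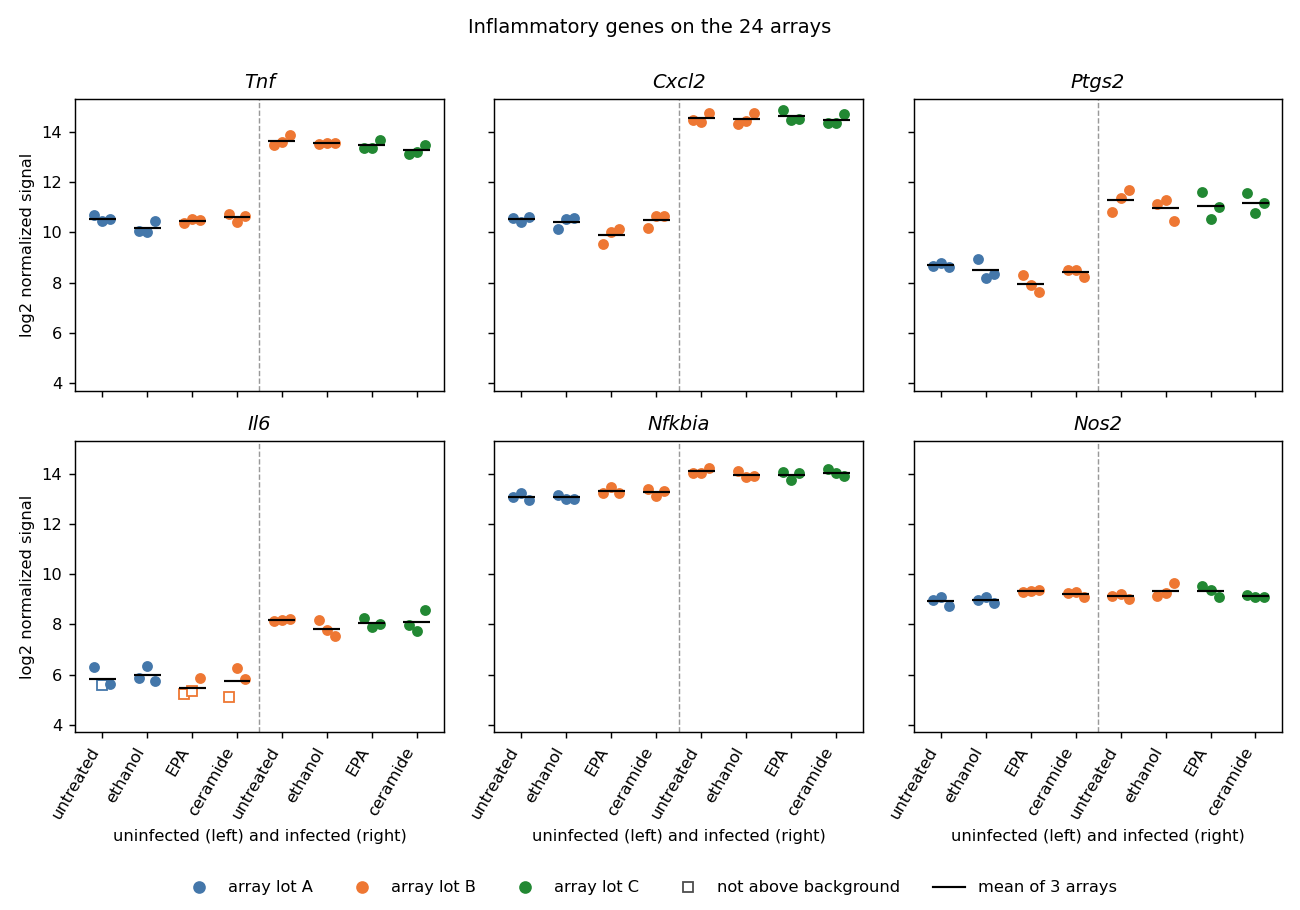
Log2 normalized signal of 6 inflammatory genes on each of the 24 arrays, by treatment, with uninfected groups on the left and infected groups on the right of each panel. Each point is 1 array, bars are means of 3 arrays, colours are array lots and open squares are arrays not above background; Tnf averages 3.03 log2 units higher and Cxcl2 4.20 higher with infection, and Nos2 0.12 higher.

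The immediate early genes, transcription factors and signal modulators that cells induce within minutes, rose as a group. Of 44 members tested, 33 rose, 4 fell and 7 did not pass, with a median log2 difference of 0.52 (limma camera, adjusted p = 7.28e-18). Phlda1 rose 9.62-fold, the transcription factor Egr2 6.91-fold, and Zfp36, whose protein destabilizes cytokine messages, 4.59-fold. The fallers were Dusp6 (-0.61), Nr4a3 (-0.40), Klf10 (-0.34) and Cebpd (-0.24). Inflammatory cytokines and chemokines had 21 of 31 members rise and 0 fall (median 0.51, adjusted p = 7.28e-18). Beside Cxcl2 and Tnf these included Cxcl3 (log2 difference 2.51), Ccl3 (1.22) and Ccl2 (0.40). Of 31 NF-kB regulators and targets with a value in the averaged comparison, 20 rose and 1 fell (median 0.32, adjusted p = 9.27e-13). The surface marker Cd83 rose 3.45-fold, the caspase 8 inhibitor Cflar 2.56-fold, and Traf1 rose by 1.22 log2 units, and Tnip2 fell by 0.29. Members beyond the leading 3 of a list were picked after their values were seen. These 3 lists also passed with an estimated correlation, at adjusted p = 1.46e-05 for the immediate early genes, 0.000383 for the cytokines and 0.00862 for the NF-kB list. When adjusted over the list alone, the counts were 33 up and 5 down, 23 up and 0 down, and 22 up and 1 down.

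Interferon stimulated genes moved the other way after infection. Of 39 members, 20 fell, 4 rose and 15 did not pass (median -0.23, adjusted p = 0.032; adjusted p = 0.629 with an estimated correlation and 0.0547 with the mean over a gene's probes). The antiviral genes Mx2 (-0.88, standard error 0.11, adjusted p = 8.41e-06), Mx1 (-0.79) and Oas2 (-0.67) fell, and Stat2, which carries the interferon signal to the nucleus, fell by 0.80. Ifnb1 itself rose 1.86-fold (adjusted p = 7.63e-05), with Gbp2, dim in uninfected cells, Xaf1 (0.30) and Irf1 (1.07, standard error 0.36, adjusted p = 0.0259). The call for Irf1 ended when the 2 arrays with the highest 75th percentile of signal were left out. Pattern recognition and phagocytic receptors had 15 members rise and 5 fall of 42 (median 0.11, adjusted p = 0.0201; adjusted p = 0.629 with an estimated correlation). The mycobacterial glycolipid receptor gene Clec4e rose 2.42-fold, Nlrp3 1.83-fold and Tlr2 by 0.66 log2 units.

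Other genes of defence and stress also changed with infection, though their lists as a whole did not pass. Gadd45a, induced by damage and stress, rose 3.30-fold, Ppp1r15a, which reverses the translation block of the stress response, 2.43-fold, and Rab20, a small GTPase of maturing phagosomes, 2.16-fold. Hif1a (log2 difference 1.05, standard error 0.19), the glucose transporter gene Slc2a1 (0.81) and the cystine transporter gene Slc7a11 (0.64) rose. Txnip, which restrains glucose uptake, fell to 50.9 percent of the uninfected level (-0.97, standard error 0.04, adjusted p = 5.8e-12), and the lipase inhibitor gene Angptl4 fell by 0.70 log2 units. Among lipid genes, Fdft1, which commits farnesyl units to sterols, rose 1.75-fold, and Mylip, whose protein degrades the LDL receptor, fell by 0.47. For sphingolipids, Gla and Sgms1 each rose by 0.70 and Ormdl3, a brake on ceramide synthesis, fell by 0.61. Apoc1 (-0.42) and Mgst1 (-0.68) fell and Mrc1 rose by 0.59. The collagen chaperone gene Serpinh1 fell 3.23-fold on the probe tested, while a second probe of that gene gave a log2 difference of 0.17 and passed in the other direction in ethanol treated cells (1.13, adjusted p = 0.0492, against -2.46).

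For the remaining lists, the shift with infection did not pass in the averaged comparison (limma camera). Lipid lists gave these counts of members higher, lower and not passing. Cholesterol synthesis and SREBP2 targets had 3, 5 and 15, LXR targets 2, 5 and 12, and PPAR targets and fatty acid oxidation 2, 6 and 20. Fatty acid synthesis and desaturation had 4, 5 and 15, sphingolipid metabolism 3, 7 and 24, and eicosanoid enzymes and receptors 5, 8 and 12. Stress lists ran from 8 higher and 4 lower of 35 for endoplasmic reticulum stress and amino acid response to 3 and 6 of 19 for heat shock genes. NRF2 and metal stress genes had 5 higher and 6 lower of 32, hypoxia and glycolysis 7 and 3 of 27, and apoptosis and survival 9 and 7 of 32. In the phagocytic machinery, the phagosome and NADPH oxidase list had 4 higher and 8 lower of 33, the lysosome list 2 and 12 of 43, autophagy 5 and 7 of 27, and the actin and phagocytic cytoskeleton list 4 and 8 of 41. Alternative activation genes had 4 higher and 1 lower of 17, the cell cycle list 7 and 9 of 45, ribosomal proteins 6 and 2 of 29, and oxidative phosphorylation 3 and 9 of 36.

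Macrophage identity genes were bright on these arrays, with a median log2 level of 12 and Lyz2 at 14.4. With infection 2 of them rose and 8 fell of 22 (Cd14 0.31, Itgam -0.38, Cebpa -0.32), and the list shift did not pass. Itgam and Cebpa lost their calls with median scaling. Cebpa also lost it without the 2 arrays of highest 75th percentile and without any 1 of uninfected untreated array 2, EPA array 1 or 2 or ceramide array 1, or of infected untreated array 1, ethanol array 3, EPA array 1 or ceramide array 1. Markers of other cells had median levels from 5.76 for endothelial to 7.23 for T cell and B cell genes. Single markers were brighter, with Cd79a (B cell) and Cd5 (T cell) at 11.07, Tpsb2 (mast cell) at 10.85 and Mmp8 (neutrophil) at 9.69. The brightest markers of the remaining cell types ran from 7.01 (Alas2) to 8.46 (Loxl1). Of the T cell markers 3 rose and 0 fell of 6 tested (Il7r 0.49), of the B cell markers 2 rose and 1 fell of 8 (Blk), and of the fibroblast markers 2 rose and 1 fell of 6 (Col1a2). Epithelial (Cldn3 0.27) and endothelial (Esam 0.22) markers had 1 rise each, erythroid markers 1 fall (Alas2 -0.92), neutrophil markers 3 falls (Cxcr2) and mast cell markers 1 rise and 2 falls (Tpsab1 0.28, Mcpt4 -0.31). Blk, Col1a2 and Cxcr2 were below background in whole groups, so no size is given. None of these list shifts passed.

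The arrays fall into 3 sets by the probes that recurrently carry the letter U. These sets are called lots here, although the labels name none and what they stand for is not known. They do not cross the design evenly. Untreated and ethanol uninfected samples were on lot A, EPA and ceramide infected samples on lot C, and the other 4 groups on lot B, so each comparison of infected with uninfected cells within a treatment crosses lots. Cxcl2 rose by 4.05 between lots A and B (untreated and ethanol) and by 4.35 between lots B and C (EPA and ceramide). Tnf rose by 3.23 and 2.82, Il6 by 2.09 and 2.47, and Egr2 by 2.84 and 2.74. On lot B alone, infected untreated and ethanol cells against uninfected EPA and ceramide cells, Cxcl2 was higher by 4.32, Tnf by 3.06, Ptgs2 by 2.94 and Il6 by 2.38. That comparison, which also contains the lipid difference, passed for 6167 of 24789 probes. Of these, 5613 also passed in the averaged comparison. The averaged comparison includes the same lot B arrays and called 40.1 percent of its probes, so this overlap is no separate support. Immediate early genes (29 rose and 3 fell of 44), cytokines (19 and 0 of 31) and NF-kB genes (15 and 1 of 32) passed there as lists, with an estimated correlation too (the highest adjusted p = 0.0198). Interferon stimulated genes were lower (2 rose and 15 fell, adjusted p = 0.0101; adjusted p = 0.5 with an estimated correlation) and cholesterol genes higher (8 rose and 1 fell, adjusted p = 0.00152; adjusted p = 0.0636 with an estimated correlation). Between the 2 lot steps, which share no arrays, 2876 probes passed in the same direction (1384 up and 1492 down, against 337.1 and 437 expected by independent overlap) and 55 in opposite directions. Passing both steps upward were 25 of 44 immediate early genes, 18 of 31 cytokines and 12 of 32 NF-kB genes, and downward 9 of 39 interferon stimulated genes. Among the averaged falls, Endou, Pla2r1, Has2 and Cd24a were above background on no lot C array and did not pass in untreated or ethanol treated cells.

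In untreated macrophages (3 infected and 3 uninfected arrays), infection raised Cxcl2 16.2-fold, from a log2 level of 10.53 (SD 0.09) to 14.54 (SD 0.17, adjusted p = 8.92e-11). Tnf rose 8.53-fold and Ccrl2, a chemerin-binding receptor gene, 7.42-fold, both at adjusted p = 8.92e-11. Egr2 rose 10.1-fold, Ptgs2 6.10-fold, Zfp36 4.80-fold and Cflar 3.24-fold. Il6 rose 5.05-fold, with 2 of 3 uninfected arrays above background, and Egr1 rose at least 2.53-fold. Il1b rose at least 4.70-fold. Gpc4, a cell surface proteoglycan gene, fell at least 3.72-fold, and Txnip (-0.96), Angptl4 (-0.75), Mx1 (-0.67) and Oas2 (-0.62) fell. Mx1 and Oas2 lost their calls with median scaling and without uninfected array 2, and Mx1 also without uninfected array 1, without infected array 1, 2 or 3 and without the filter on dim probes. Of 24755 probes, 664 rose and 742 fell, and with median scaling 725 rose and 493 fell. Leaving out uninfected array 1 or 2 brought the 1406 calls to 800 or 844, and leaving out infected array 1 or 2 to 917 or 818. Immediate early genes had 21 rise and 2 fall of 44, cytokines 14 rise of 31 and NF-kB genes 14 rise and 1 fall of 32 (median 0.61, adjusted p = 1.08e-20). Pattern recognition receptors passed at adjusted p = 0.0274, and adjusted p = 0.483 with an estimated correlation.

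In ethanol treated macrophages, the vehicle control, Cxcl2 rose 16.9-fold (adjusted p = 6.31e-11) and Tnf 10.4-fold, from 10.18 (SD 0.24) to 13.55 (SD 0.01). Phlda1 rose 8.61-fold, Ccrl2 6.71-fold and Ptgs2 5.55-fold. Il6 rose 3.61-fold, Il1b at least 3.13-fold and the collagenase gene Mmp13 at least 3.83-fold. Rgs1, a brake on chemokine receptor signalling, rose 10.4-fold with 1 of 3 uninfected arrays above background. Hoxc8 fell at least 2.09-fold and Sox5 at least 1.98-fold, and Txnip (-0.88) and Angptl4 (-0.86) fell again, Angptl4 losing its call with only the groups compared. In this comparison 1967 probes rose and 2410 fell, and with median scaling 2011 rose and 1103 fell. The 4377 calls became 2287 or 2286 without uninfected array 1 or 2, 1880 without infected array 3 and 230 with only the groups compared. Immediate early genes had 20 rise and 2 fall, cytokines 15 rise, and NF-kB genes 15 rise and 1 fall (adjusted p = 1.08e-12). The receptor list had 9 rise and 1 fall (adjusted p = 0.0171, and adjusted p = 0.726 with an estimated correlation; 0.0518 with median scaling).

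In EPA treated macrophages the 2 leading rises were Nfkbiz, at least 23.1-fold, and Cxcl2, 26.4-fold, from 9.89 (SD 0.33) to 14.62 (SD 0.21, adjusted p = 8.77e-12). Phlda1 rose 15.6-fold, Ptgs2 8.53-fold, Tnf 7.96-fold and Il6 6.00-fold, Il6 with 1 of 3 uninfected arrays above background. Gadd45a rose 4.54-fold and Ppp1r15a 2.56-fold. Il10, an anti-inflammatory cytokine, rose 1.88-fold (adjusted p = 0.0225), and that call ended without the 2 arrays of highest 75th percentile, without uninfected array 1 or infected array 1 or 2, and with only the groups compared. Txnip fell by 1.09 log2 units and Mx2 by 1.00. Mx2 lost its call without uninfected array 1, with median scaling and with only the groups compared, and Gadd45a with the last of these. In all, 1108 probes rose and 1292 fell of 24739. Median scaling moved the median of all probes from -0.0229 to 0.1077 and the split to 2602 up and 663 down. The 2400 calls became 1033 or 951 without uninfected array 1 or 2 and 1546 without infected array 1. They became 200 with only the groups compared, 1596 without the filter on dim probes and 10928 with array weights. Cytokines had 17 rise and 0 fall (adjusted p = 7.22e-19) and immediate early genes 20 rise and 3 fall (adjusted p = 5.5e-15). NF-kB genes had 9 rise and 0 fall (median 0.21, adjusted p = 4.61e-07; adjusted p = 0.087 with an estimated correlation), and receptors 8 rise and 1 fall (adjusted p = 0.00594; adjusted p = 0.523 with an estimated correlation).

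In ceramide treated macrophages infection raised Cxcl2 15.8-fold (adjusted p = 1.95e-10), Phlda1 10.9-fold, Egr2 7.16-fold and Ptgs2 6.71-fold. Tnf rose 6.30-fold, from 10.61 (SD 0.17) to 13.27 (SD 0.18), Cxcl3 6.22-fold and Il6 5.11-fold, Il6 with 2 of 3 uninfected arrays above background. Ifnb1 rose 2.26-fold (adjusted p = 0.0166), a call that ended without the 2 arrays of highest 75th percentile, without uninfected array 1 or infected array 1, and with only the groups compared. Nlrp3 rose 2.20-fold and Il7r 1.91-fold, and Txnip (-0.97), Mx1 (-0.86) and Mylip (-0.57) fell. Mx1 lost its call without infected array 3, Mx1 and Il7r with only the groups compared, and Mylip with median scaling. The count was 664 up and 791 down of 24739. Median scaling moved the median of all probes from -0.0149 to 0.1079 and the split to 1377 up and 490 down, and the 1455 calls became 602 with only the groups compared. They became 720, 861 or 798 without uninfected array 1, 2 or 3 and 935 or 854 without infected array 2 or 3. Immediate early genes had 23 rise and 1 fall (median 0.65, adjusted p = 2.08e-23), cytokines 12 rise (adjusted p = 2e-15) and NF-kB genes 11 rise (adjusted p = 2.47e-09). Interferon stimulated genes had 1 rise and 7 fall (median -0.26, adjusted p = 0.000477; adjusted p = 0.327 with an estimated correlation). The stress list had 4 rise and 0 fall (adjusted p = 0.0192; adjusted p = 0.501 with an estimated correlation).

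**Figure D2:**
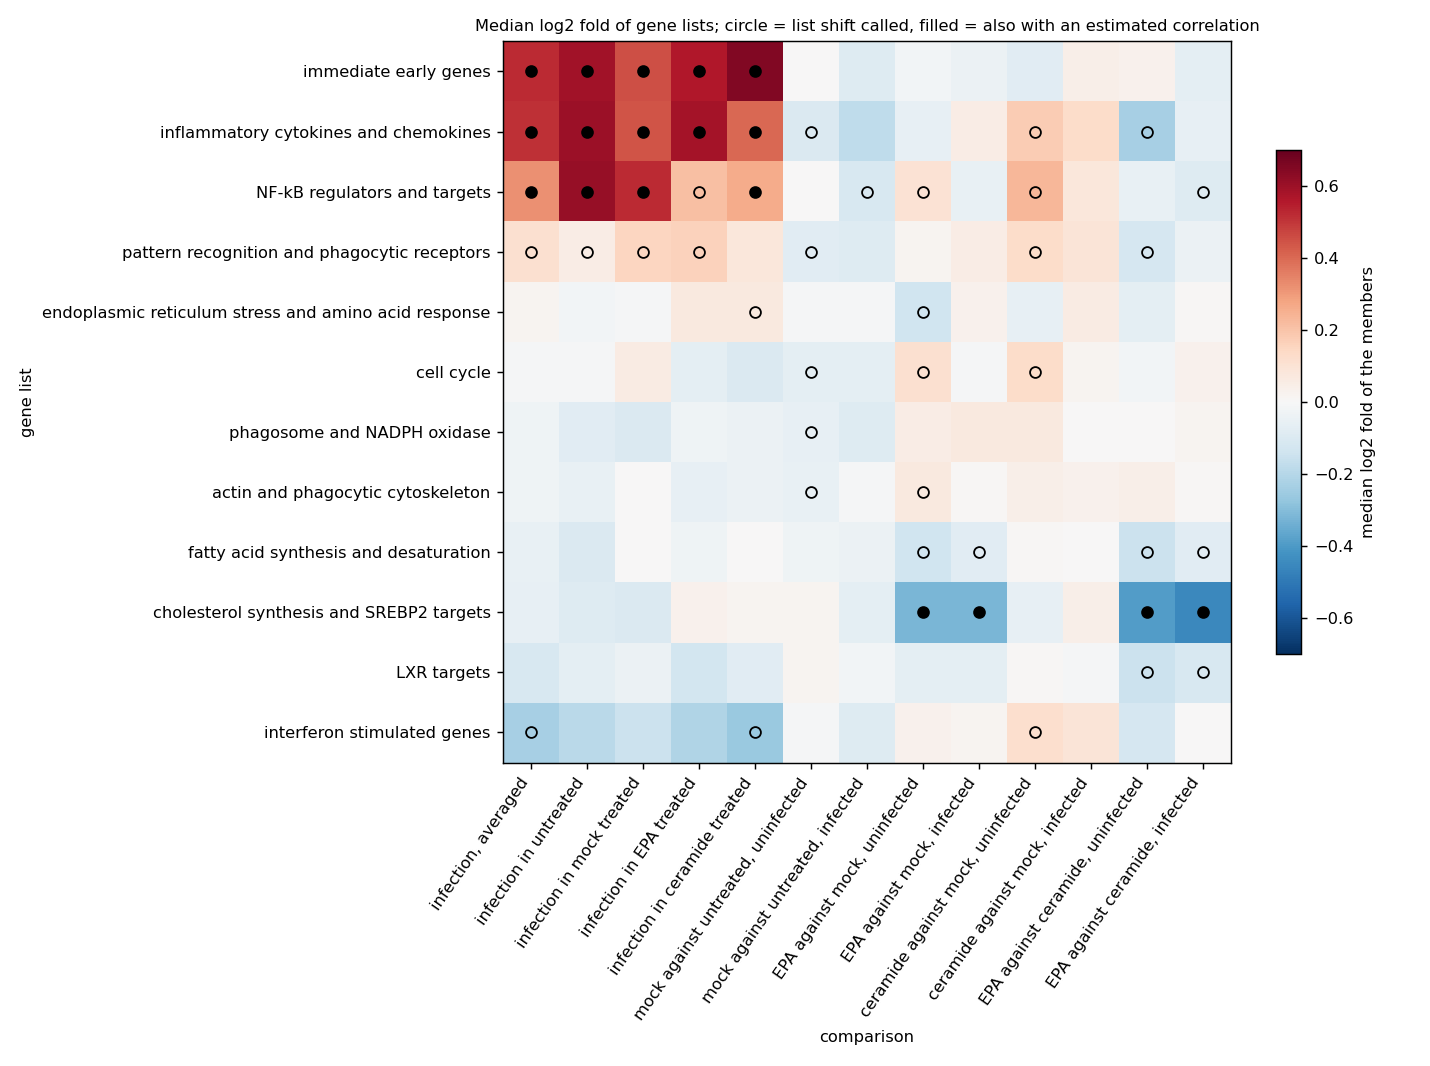
Median log2 fold of the members of 12 gene lists (vertical axis) in 13 comparisons (horizontal axis), 3 arrays per group. Colour runs from lower (blue) to higher (red), circles mark list shifts that passed at an adjusted p of 0.05 and filled circles those that also passed with an estimated correlation; the filled circles lie in the inflammatory lists with infection and in the cholesterol list with EPA (median -0.39 against ceramide in uninfected cells).

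No single inflammatory gene passed for ethanol alone against untreated cells. Tnf differed by -0.38 in uninfected cells (95 percent interval -0.67 to -0.08, adjusted p = 0.642) and by -0.09 in infected cells. Cxcl2 differed by -0.11 (interval -0.48 to 0.27) and -0.04 (interval -0.42 to 0.33). The mitotic kinesin gene Kif23, lower by 1.63 log2 units (adjusted p = 0.385), and the oxidase subunit gene Cybb, lower by 1.06 (adjusted p = 0.484), did not pass. In limma 0 of 24789 probes passed in either state, with 1714 and 1551 at an unadjusted p under 0.05 against 1239 expected, and within-lot arrays were compared in both. In uninfected cells 3 or 2 passed without untreated array 1 or 3, and 2, 1 or 11 without ethanol array 1, 2 or 3. In infected cells 1 or 2 passed without untreated array 1 or 3, and 2, 1 or 1 without ethanol array 1, 2 or 3. In uninfected cells 5 lists shifted down by small amounts. These were cell cycle (median -0.07, adjusted p = 0.000284; adjusted p = 0.322 with an estimated correlation), cytokines (-0.10, adjusted p = 0.00277; adjusted p = 0.322 with an estimated correlation) and phagosome (-0.06, adjusted p = 0.00277; adjusted p = 0.322 with an estimated correlation). Actin genes gave adjusted p = 0.018 (adjusted p = 0.673 with an estimated correlation) and receptors adjusted p = 0.018 (adjusted p = 0.634 with an estimated correlation). In infected cells NF-kB genes shifted by -0.11 (adjusted p = 0.0482; adjusted p = 0.439 with an estimated correlation).

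With EPA, an omega-3 fatty acid given 3 h before at 15 µM, genes of lipid synthesis were lower than with ethanol in uninfected macrophages. Lpin1, which makes the diacylglycerol used for triglycerides, fell 4.06-fold against ethanol, from 9.62 (SD 0.27) to 7.60 (SD 0.24, adjusted p = 5.99e-07). A second, dim probe of Lpin1 gave -0.48 and did not pass (limma, adjusted p = 0.755). Hmgcs1, an early enzyme of cholesterol synthesis, fell 3.09-fold (standard error 0.12 log2 units, adjusted p = 7.95e-07). Later enzymes of that route fell as well, Mvd by 0.69, Hsd17b7 by 0.61, Pmvk by 0.54 and Cyp51 by 1.05 (adjusted p = 0.0189). Of 23 cholesterol synthesis and SREBP2 targets, 6 fell and 0 rose, and 13 fell when adjusted over the list alone (median -0.32, adjusted p = 1.29e-16). That shift passed with an estimated correlation too (adjusted p = 8.61e-05). Ceramide, on the same lot as EPA, differed from ethanol by -0.85 for Hmgcs1, -0.39 for Lpin1 and -0.33 for Cyp51, with a list median of -0.06. Of these 3 genes Hmgcs1 alone passed for ceramide. Other members were higher with ceramide than with ethanol, such as Msmo1 (0.34), and in infected cells Lpin1 (0.21) and Cyp51 (0.31) were too. So a fall with ceramide was called for Hmgcs1 only. Whether ceramide, the lot or the level of the shared ethanol arrays gave it was not separated. Beyond lipids, the stress kinase gene Plk2 fell 2.66-fold, Hs3st1 2.34-fold, Tcim 2.03-fold and Rgs2 1.73-fold. Trib3 (-0.65) and Ddit3 (-0.51), both of the amino acid and stress response, fell, and Cdc42ep2 rose 1.56-fold. Plin2 was higher by 0.49 (interval 0.10 to 0.87, adjusted p = 0.328), Cxcl2 lower by 0.53 (adjusted p = 0.273) and Ccl3 lower by 0.50 (adjusted p = 0.0725).

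That comparison, lot B against lot A, passed for 13 probes up and 61 down of 24755 in limma. With only the groups compared 0 passed, with array weights 1589 were higher and 1638 lower (3227 in all), and without ethanol array 3 48 were higher and 52 lower. Without ethanol array 1 or 2 44 or 27 passed, and without EPA array 2 or 3 41 or 43. The calls for Cyp51, Trib3, Ddit3, Avil and Cdkn2b ended in each of these 4 fits, and those for Ddit3 and Cdkn2b also without EPA array 1. Cnot9 kept its call without ethanol array 1 alone. Phf2, at least 2.20-fold higher with EPA, was above background on all 12 lot B arrays and on no array of lots A and C, and Crabp1 (-1.82) and Avil (-1.68) were lower on lots B and C alike. Cdkn2b was at least 1.67-fold higher (adjusted p = 0.0372) and Cnot9 higher by 0.95 (adjusted p = 0.0478). Endoplasmic reticulum stress genes, Trib3 and Ddit3 among them, had 2 fall and 33 not pass (median -0.14, adjusted p = 0.00315; adjusted p = 0.598 with an estimated correlation). Fatty acid synthesis shifted down (-0.14, adjusted p = 0.0241; adjusted p = 0.352 with an estimated correlation). Cell cycle (0.11, adjusted p = 0.00221; adjusted p = 0.352 with an estimated correlation), NF-kB (0.10, adjusted p = 0.00345; adjusted p = 0.567 with an estimated correlation) and actin genes (0.07, adjusted p = 0.00483; adjusted p = 0.615 with an estimated correlation) shifted up, and 5 NF-kB genes were higher when adjusted over the list alone. With median scaling none of these upward shifts passed (limma camera, adjusted p = 0.117, 0.0722 and 0.76 in the same order). Against untreated cells, the same ethanol arrays had the cell cycle and actin lists shifted down, and the NF-kB list did not pass there. Whether EPA, the level of these ethanol arrays or the lot gave the upward shifts was not separated.

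In infected macrophages genes of lipid synthesis were lower with EPA than with ethanol, lot C against lot B. Lpin1 fell 3.04-fold, from 9.52 (SD 0.11) to 7.91 (SD 0.12, adjusted p = 4.54e-06), Hmgcs1 1.72-fold (adjusted p = 0.00494), Mvd by 0.58, Pmvk by 0.47 and Msmo1 by 0.66 (adjusted p = 0.04). The second probe of Lpin1 gave -1.26 here and did not pass (limma, adjusted p = 0.39). Of 23 cholesterol genes 5 fell and 0 rose, and when adjusted over the list alone 11 fell and 1 rose (median -0.32, adjusted p = 2.33e-14). The shift passed with an estimated correlation (adjusted p = 0.000209). Lbh, a transcription cofactor gene, rose 1.80-fold on the probe tested (adjusted p = 0.00164), with 0.26 on a second probe (adjusted p = 0.454), and also passed for the 2 lipids jointly (0.65), the lot C contrast. The autophagy receptor gene Nbr1 rose 1.38-fold. The mast cell marker Tpsab1 fell by 0.44. The inflammatory response itself showed no passing difference. Tnf differed by -0.09 (interval -0.38 to 0.21), Cxcl2 by 0.12 (interval -0.26 to 0.50), Il6 by 0.24 (interval -0.34 to 0.83), Il1b by -0.04 (interval -0.76 to 0.68) and Plin2 by 0.29 (interval -0.10 to 0.67). In limma 7 probes rose and 30 fell of 24739, or 11 and 22 with median scaling, and 0 passed with only the groups compared. With array weights 209 were higher and 307 lower (516 in all). Without ethanol array 1, 2 or 3 the rises were 13, 25 or 19 and the falls 30, 29 or 30. Msmo1 lost its call without ethanol array 1 or 3 or EPA array 2 or 3, Nbr1 without ethanol array 3 or EPA array 1 or 3, and Tpsab1 without EPA array 3. Fatty acid synthesis shifted down (adjusted p = 0.0485; adjusted p = 0.367 with an estimated correlation).

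With ceramide, given at 5 µg/ml, few genes differed from ethanol in uninfected macrophages. The comparison set lot B against lot A, so ceramide and lot cannot be told apart in it. Acod1, which makes itaconate, rose 1.83-fold against ethanol, from 9.64 (SD 0.11) to 10.50 (SD 0.22, adjusted p = 0.0183), and the histone gene H2bc8 rose 1.57-fold. Agap1, an Arf GTPase regulator, fell 1.81-fold (adjusted p = 0.00275), Hmgcs1 1.81-fold (adjusted p = 0.00898), Pdlim4 1.57-fold and the transporter gene Slc46a3 1.53-fold. Tnf was higher by 0.44 (interval 0.14 to 0.73, adjusted p = 0.264), Traf1 by 0.48 (adjusted p = 0.0567), Usp18 by 0.54 (adjusted p = 0.0936) and Cxcl10 by 0.61 (adjusted p = 0.133). The NF-kB list shifted up (0.23, adjusted p = 3.56e-06; adjusted p = 0.196 with an estimated correlation), as did cytokines (0.18, adjusted p = 0.000172; adjusted p = 0.196 with an estimated correlation). Receptors (0.13, adjusted p = 0.000172; adjusted p = 0.236 with an estimated correlation), cell cycle (0.13, adjusted p = 0.000948; adjusted p = 0.252 with an estimated correlation) and interferon stimulated genes (0.12, adjusted p = 0.00304; adjusted p = 0.378 with an estimated correlation) did too. Against untreated cells, the same ethanol arrays had the cytokine, receptor and cell cycle lists shifted down. The NF-kB and interferon stimulated lists did not pass there. Whether ceramide, the level of these ethanol arrays or the lot gave the upward shifts was not separated. When adjusted over the list alone, 5 NF-kB, 4 interferon stimulated and 2 cytokine genes were higher. In limma 4 probes rose and 7 fell of 24755, with 2506 at an unadjusted p under 0.05. Phf2, with its lot B pattern, was among the rises. With only the groups compared 0 passed and with array weights 303. Without ethanol array 1, 2 or 3 8, 4 or 22 probes were higher and 5, 1 or 8 lower, so the balance of rises and falls turned, and without ceramide array 3 6 passed. Leaving out ethanol array 2 ended the calls for Hmgcs1, Acod1, H2bc8, Pdlim4 and Slc46a3. The last 4 also ended without ceramide array 3, Acod1, Pdlim4 and Slc46a3 without ethanol array 1, Acod1 and Pdlim4 without ceramide array 2, Pdlim4 without ethanol array 3 and H2bc8 without ceramide array 1.

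Infected macrophages given ceramide had Bnip3, a mitophagy gene, 1.67-fold higher than with ethanol (adjusted p = 0.0352), and Evl, an actin regulator, 1.88-fold lower (adjusted p = 0.00461, with 1 of 3 ceramide arrays above background). Bnip3 lost its call without each single array of these groups but ethanol array 2. Tnf differed by -0.28 (interval -0.58 to 0.01) and Cxcl2 by -0.02 (interval -0.40 to 0.35). No list shift passed. Of 24739 probes 6 rose and 27 fell, with 2979 at an unadjusted p under 0.05, and 8 passed with only the groups compared, 59 with array weights and 51 without ethanol array 2, 29 of the 51 higher and 22 lower. Without ethanol array 3 14 were higher and 17 lower. The largest of these differences were shared with EPA. Ptgis, prostacyclin synthase, was at least 8.14-fold higher with ceramide and at least 7.64-fold higher with EPA. Endou, an RNA endonuclease gene, was at least 12.4-fold and 11.9-fold lower, Pla2r1 at least 5.31-fold and 4.77-fold, the hyaluronan synthase gene Has2 at least 4.00-fold and 3.85-fold, and Cd24a at least 3.24-fold and 3.12-fold. Epor was at least 1.89-fold and 1.68-fold higher, the last with 2 of 3 EPA arrays above background. Ephb6 fell by 2.01 and 1.74 log2 units, with 1 of 3 arrays above background in each lipid group.

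On single arrays these shared genes followed the lot. Endou was above background on all 18 arrays of lots A and B, at 8.7 to 9.3, and on no lot C array. Ptgis was above background on the 6 lot C arrays alone, at log2 8.15 to 8.64. Taking EPA and ceramide together against untreated and ethanol in infected cells, a comparison added after the lots were seen, 40 probes were higher and 80 lower, 35 of them by 2-fold or more. Of the 120, 117 had the same sign for both lipids against ethanol. The 120 were picked on the mean of both lipids, and the ethanol arrays were shared, so like signs were favoured in advance. The 35 had a median absolute difference of 1.426 from the controls and of 0.1815 between the lipids, and 0 of them passed for EPA against ceramide. That 0 says little, since 8 of 24777 probes passed for EPA against ceramide in infected cells and 6 of 24789 in uninfected cells. In uninfected cells the same contrast, lot B against lot A, gave 126 probes higher and 214 lower.

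**Figure D3:**
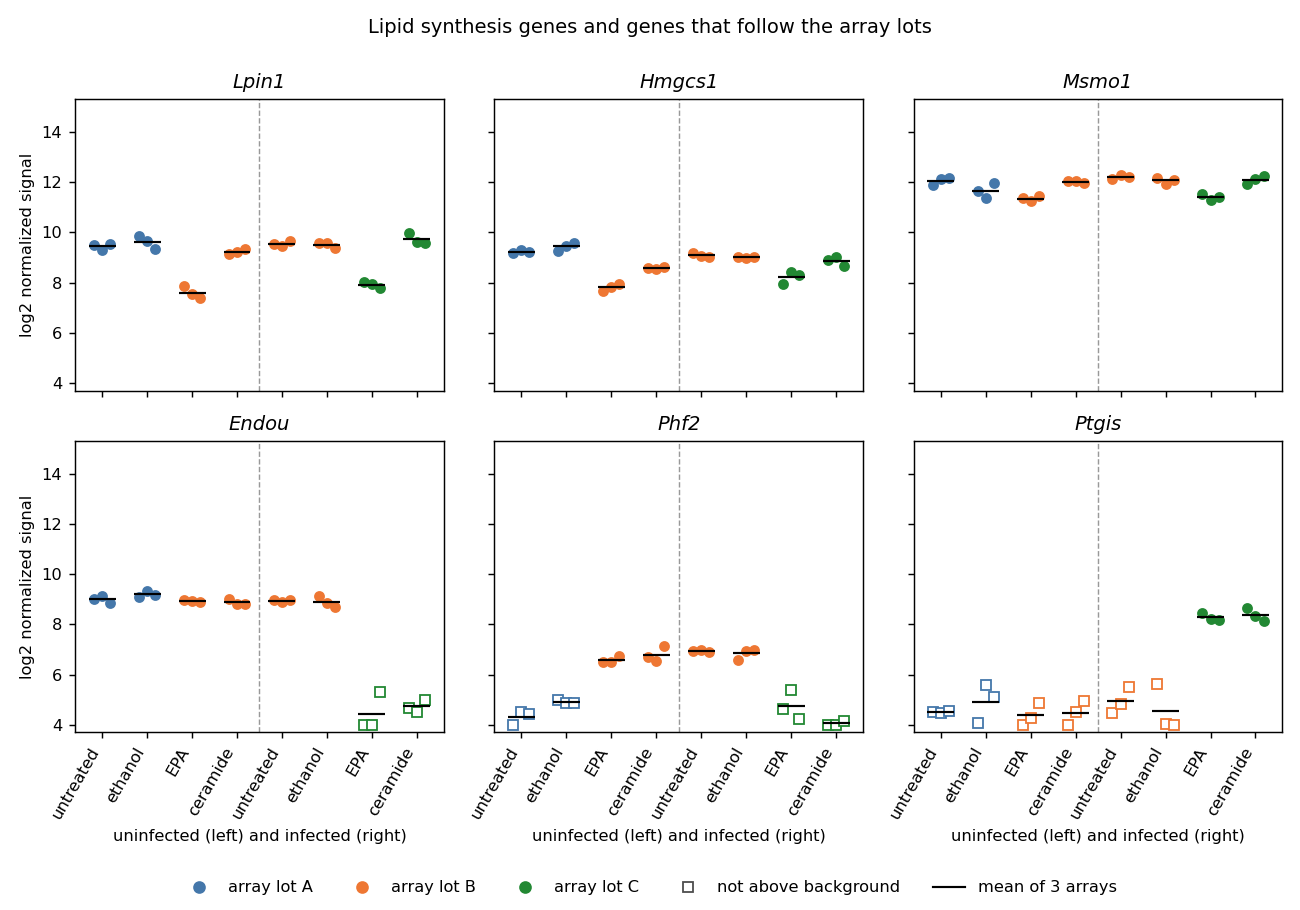
Log2 normalized signal of 3 lipid synthesis genes (top) and 3 genes that followed the array lots (bottom) on each of the 24 arrays, with uninfected groups on the left and infected groups on the right of each panel. Each point is 1 array, bars are means of 3 arrays, colours are array lots and open squares are arrays not above background; Lpin1 is 1.72 log2 units lower with EPA than with ceramide, and Endou, Phf2 and Ptgis change where the lot changes.

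The sets called for EPA and for ceramide against the same ethanol arrays overlapped. In uninfected cells Phf2 and 1 other probe were higher with both, and 5, Hmgcs1 among them, were lower with both, against 0.002101 and 0.01725 expected by independent overlap. In infected cells 3 were higher and 16 lower with both, against 0.001698 and 0.03274. Independent overlap leaves out the shared ethanol arrays, which number 3 per state and cannot be divided, so part of the excess may come from them. Simulated unchanged groups against shared controls overlapped in 0 probes in 100 runs, but such data hold almost no calls and give no measure for these counts. Across probes the covariance of the 2 sets of differences was 0.04976 in uninfected and 0.05071 in infected cells, against 0.02784 simulated (correlations 0.6279 and 0.6814, against 0.4997). EPA and ceramide also shared their lot in each state, which the simulation did not contain.

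EPA and ceramide were on the same lot in each state, and the cholesterol genes differed between them in both. Lpin1 was 3.09-fold lower with EPA than with ceramide in uninfected cells (adjusted p = 2.25e-05) and 3.51-fold lower in infected cells, at 7.91 (SD 0.12) against 9.73 (SD 0.23, adjusted p = 3.79e-06). A second, dim probe of Lpin1 gave -0.23 and -0.55 and did not pass. In uninfected cells Plk2 was 2.23-fold lower (adjusted p = 0.00283), and Hmgcs1 (-0.77), Tcim (-0.80), Efr3b (-0.54) and the chemokine gene Ccl3 (-0.70, adjusted p = 0.031) were lower. In infected cells Aacs, which turns ketone bodies into lipid precursors, was lower by 0.59 and the chloride transporter gene Clcn6 by 0.53 (adjusted p = 0.0328 for both), with -0.19 on a second probe of Clcn6 (adjusted p = 1). Of 23 cholesterol genes, 21 were lower with EPA in both states. The list shifted by a median of -0.39 in uninfected cells (2 fell, 13 when adjusted over the list alone, adjusted p = 8.81e-21) and of -0.45 in infected cells (1 and 13, adjusted p = 1.22e-25). Both shifts passed with an estimated correlation, at adjusted p = 2.08e-05 and 5.14e-06.

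Averaged over both states, a comparison added after the lots were seen, 33 probes were lower with EPA and 0 higher. Of the 33, 24 were the brightest tested probe of a named gene. Lpin1 was lower by 1.72 (standard error 0.10, adjusted p = 2.41e-08), Rdh11, a retinal reductase gene, by 0.86, Hmgcs1 by 0.71, Msmo1 by 0.67 and Nsdhl by 0.61. Mvd, Idi1 and Hsd17b7 were each lower by 0.45 and Pmvk by 0.43. Chac1 was lower by 0.69 (adjusted p = 0.0417) and Ddit3 by 0.44 (adjusted p = 0.015), the 2 passing members of 35 in the endoplasmic reticulum stress list (median -0.03, adjusted p = 0.0339; adjusted p = 0.71 with an estimated correlation). Cholesterol genes had 8 lower and 15 not passing, with 15 lower when adjusted over the list alone (median -0.43, adjusted p = 1.03e-30). Fdft1 (-0.69, adjusted p = 0.197), Cyp51 (-0.63, adjusted p = 0.103) and Lss (-0.54, adjusted p = 0.0539) did not pass, and the regulators Insig2 (-0.01) and Scap (0.02) differed little. With an estimated correlation the averaged shifts of fatty acid synthesis (adjusted p = 0.042) and LXR targets (median -0.14, adjusted p = 0.0366) passed as well as that of cholesterol genes (adjusted p = 1.49e-06).

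**Figure D4:**
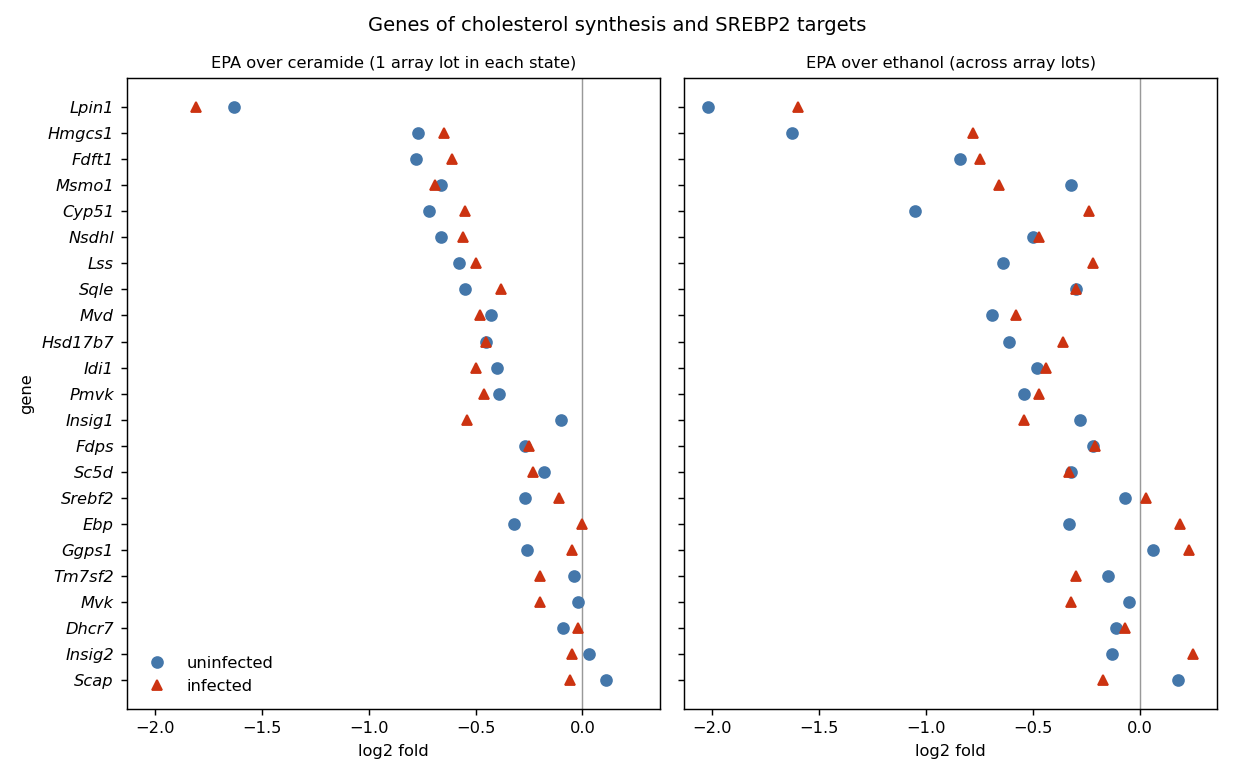
Log2 fold (horizontal axis) of 23 genes of cholesterol synthesis and SREBP2 targets (vertical axis) for EPA over ceramide (left) and EPA over ethanol (right). Each point is the difference of 2 group means of 3 arrays, circles for uninfected and triangles for infected cells; 21 genes are lower with EPA than with ceramide in both states and 18 lower than with ethanol in both.

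Other lists differed between EPA and ceramide by small amounts. In uninfected cells cytokines, Ccl3 among them, were lower with EPA (median -0.23, adjusted p = 6.54e-06; adjusted p = 0.0718 with an estimated correlation), as were fatty acid synthesis (-0.15, adjusted p = 0.00199; adjusted p = 0.0718 with an estimated correlation) and LXR targets (-0.15, adjusted p = 0.0157; adjusted p = 0.084 with an estimated correlation). Receptors passed at adjusted p = 0.00123 (adjusted p = 0.242 with an estimated correlation). In infected cells fatty acid synthesis (adjusted p = 0.0267; adjusted p = 0.221 with an estimated correlation), LXR targets (adjusted p = 0.0248; adjusted p = 0.128 with an estimated correlation) and NF-kB genes (adjusted p = 0.0348; adjusted p = 0.627 with an estimated correlation) were lower. Of 24789 probes 0 were higher and 6 lower in uninfected cells, and of 24777 probes 0 were higher and 8 lower in infected cells. With median scaling 1 passed in each state, and with only the groups compared 0. With array weights 4028 passed in uninfected cells, 1914 of them higher with EPA, and 118 in infected cells, 33 of them higher. In uninfected cells 3 or 2 passed without EPA array 1 or 2 and 3 or 2 without ceramide array 2 or 3. Hmgcs1 and Tcim kept their calls there without EPA array 3 alone, Efr3b without ceramide array 1 alone, and Ccl3 without EPA array 1 or ceramide array 1. In infected cells 2, 1 or 2 passed without EPA array 1, 2 or 3 and 1, 4 or 4 without ceramide array 1, 2 or 3. Aacs lost its call in each of these 6 fits and Clcn6 in all but that without EPA array 3. Besides Ccl3 in uninfected cells, no single member of the cytokine or NF-kB lists passed. Tnf differed by -0.14 (interval -0.43 to 0.15) and 0.20 (interval -0.09 to 0.49), Il6 by -0.26 (interval -0.84 to 0.32) and -0.03 (interval -0.61 to 0.56), Nfkbia by 0.04 and -0.09, and Plin2 by 0.21 (interval -0.17 to 0.59) and 0.29 (interval -0.09 to 0.67). The doses were 15 µM and 5 µg/ml, in different units, so the lipids were not compared at matched amounts.

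Whether a lipid changed the response to infection was tested as an interaction against ethanol, which sets lots A and C against lot B. For EPA and for ceramide Ptgis passed as higher and Endou, Phf2, Has2 and Cd24a as lower, and no size is given because each was below background in at least 1 of the groups. Genes above background in all 4 groups of the EPA interaction included Slc46a3 (0.88, standard error 0.14, adjusted p = 0.00761), the actin nucleator gene Spire1 (1.07) and Lipt2, a lipoate transferase gene (-1.64, standard error 0.14, adjusted p = 5.43e-06). For ceramide, Agap1 (1.17, standard error 0.16, adjusted p = 0.0013), Slc46a3 (1.01), Spire1 (1.04) and Hs3st1 (1.30) were higher and the peroxisome import gene Pex13 (-1.63, standard error 0.16) lower. Slc46a3 and Spire1 moved alike with both lipids, and a lot effect was not separated from these values. The inflammatory genes named next did not pass. Tnf had an interaction of -0.38 with EPA (interval -0.80 to 0.03) and of -0.72 with ceramide (interval -1.13 to -0.31, adjusted p = 0.138). Cxcl2 had 0.65 with EPA (interval 0.11 to 1.18, adjusted p = 0.356) and -0.10 with ceramide, and Hmgcs1 0.84 (adjusted p = 0.0682) and 0.72 (adjusted p = 0.114).

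In limma 12 probes were higher and 18 lower for the EPA interaction, and 21 and 23 for the ceramide interaction, of 24706. Median scaling moved the median of all probes from 0.0068 to 0.1075 for EPA. For EPA 19 passed without uninfected ethanol array 2, 18 without uninfected EPA array 2 and 19 without infected EPA array 3. For ceramide 29 or 27 passed without uninfected ethanol array 1 or 2, 26, 28 or 28 without uninfected ceramide array 1, 2 or 3, and 102 without infected ethanol array 1. Hs3st1 lost its call without each uninfected ethanol array, uninfected ceramide array 2 or 3 or infected ceramide array 1 or 2. NF-kB genes shifted down with EPA (-0.23, adjusted p = 0.00886; adjusted p = 0.9 with an estimated correlation) and with ceramide (-0.24, adjusted p = 0.0356; adjusted p = 0.767 with an estimated correlation), and cell cycle genes with EPA (-0.16, adjusted p = 0.0332; adjusted p = 0.9 with an estimated correlation). Between EPA and ceramide the infection response differed for 0 of 24739 probes, with 641 at an unadjusted p under 0.05 against 1237 expected, and for 1 without infected ceramide array 2. The interval for Tnf was -0.08 to 0.75 and for Ptgs2 -0.52 to 1.21, and cytokines shifted by 0.14 (adjusted p = 0.00158; adjusted p = 0.565 with an estimated correlation). Ethanol changed the response for 0 of 24755 probes, with 1044 at an unadjusted p under 0.05, and for 1 without infected untreated array 1 or infected ethanol array 3. Tnf was at 0.28 (interval -0.13 to 0.70). Over the 17 comparisons planned before the data were examined, 54 list shifts passed and 18 of them also passed with an estimated correlation, 42 with median scaling and 44 with the mean over a gene's probes. The 18 were the immediate early genes and cytokines in each infection comparison, the NF-kB genes in each but that of EPA treated cells, and the cholesterol genes for EPA against ethanol and against ceramide in both states. The p-values throughout measure the spread between these samples, since nothing in the sources says that the 3 of a group came from separate cultures.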

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

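The tests of the array lot and of ceramide against ethanol for the cholesterol genes, the test of lot steps for infection, and the comparisons within and between lots were chosen only after the result was seen. What drew attention first was that the response to infection differed between treatments: it differed between EPA and ethanol for 30 probes and between ceramide and ethanol for 44. For ceramide 1 of 100 splits of the arrays gave as many, the real one, and the highest other gave 15. The lots follow the groups and the splits mix lots within groups. So this count cannot tell a difference in the response from a lot effect. For EPA 6 of 100 splits gave as many, up to 3038, so chance is not excluded. What the splits with the largest counts have in common was not tested.

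A pattern among these probes was a shift shared by EPA and ceramide in infected cells, led by Endou, Has2, Pla2r1, Cd24a and Ptgis. Left out of the fit, the 2 arrays with the highest 75th percentile of signal ended fewer calls than they kept, with 77 of 120 probes still passing, which argues against these arrays as its cause. For 13 genes called in that contrast, the other probes had a median difference of -0.0059 in the called direction (interval -0.1723 to 0.2033). An effect of lot C on single probes would give this. The called probes of these 13 had a median difference of 0.382, and the 5 leading genes were not among them, so the check does not cover those. The same check on 49 probes raised or lowered by infection gave 0.1162 against 1.178 (interval 0.0044 to 0.2752, 32 in the same direction), and on 54 probes of the uninfected contrast 0.1076 (interval 0.0473 to 0.1492, 38 in the same direction), values that the interval of the 13 also holds, so this check leaves the probe effect open. Lot C and the 2 lipid groups in infected cells cannot be told apart, because the lot holds these 6 arrays and no others, and a change by lipids stays open as well.

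The lower cholesterol synthesis genes and SREBP2 targets with EPA than with ceramide (Lpin1, Hmgcs1, Msmo1, Mvd) were seen inside lot B and inside lot C. In infected cells Lpin1 alone of the list passed as a single gene. The list median was -0.3894 and -0.4483, which argues against the lot as the cause. Averaged over both states, the list median stayed at or below -0.3677 with any 1 array left out. That argues against any single array as the cause of the averaged difference, and the median within each lot was not tested in this way. Ceramide raising the genes would give the same difference, and ceramide over ethanol had list medians of -0.06397 and 0.03897, but these cross lots. So whether part of the difference comes from ceramide stays open, and lower expression of sterol synthesis genes with EPA may be a response to the fatty acid, as a hypothesis found and tested on the same arrays.

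The infection response (Cxcl2, Tnf, Il6, Egr2) crossed lots in each treatment, but in different steps. Of the probes called between lots A and B, 87.85 percent had the same sign between lots B and C, against 71.1 percent of all probes, and on lot B alone 6167 probes were called in a comparison that also holds the lipid difference, which argues against lot steps as its cause. The share of rises is another matter, since median scaling moved it by 22.94 percentage points. Quantile normalization therefore fits as a source of the near balance of rises and falls, and that balance stays open.

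Other splits of the same arrays were counted for the remaining results. For infection averaged over the treatments 1 of 100 splits gave 9907 probes, the real one, and the highest other 90. These splits also mix lots within groups, so the counts alone do not tell infection from lot. Each of the other comparisons of 3 arrays with 3 has 10 splits, which cannot give a share under 0.05. The real count and the highest other were 1406 and 1 for infection in untreated cells, 4377 and 2 with ethanol, 2400 and 2 with EPA and 1455 and 1 with ceramide. For EPA against ethanol they were 74 and 6 in uninfected and 37 and 0 in infected cells, and for ceramide against ethanol 11 and 1, then 33 and 0. For EPA against ceramide they were 6 and 1 in uninfected cells. In infected cells the real 8 was matched by another split, 2 of 10 in all. For ethanol against untreated all 10 of 10 splits gave the real 0 or more, up to 4 and 5. For the interactions with 0 real calls, EPA against ceramide and ethanol against untreated, 100 of 100 splits gave as many, up to 33 and 3.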

How the results depend on the processing

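The floor of 32, the fit without the 2 brightest arrays and the lot B comparison were chosen only after the results were seen. Of 473 calls of named genes, 0 turned direction under any alternative run. For comparisons of 2 groups, the leading rises and falls were picked for no overlap of the groups. Leaving out an array could therefore not turn those. Not every alternative was run for every call. Of those that were, leaving out arrays aside, 227 calls passed in each, and 217 also with each array left out. Array weights kept 463, the replicate block 458, the fit without the 2 brightest arrays 421, no filter on dim probes 402 and median scaling 382. Only the groups compared kept 150 of 373 calls, the stricter filter 318 of 318 and leaving out each array in turn 4157 of 4812. Infection averaged over the treatments stayed between 8943 and 10143 probes with any 1 array left out, and was 6167 within lot B. The ranges with 1 array left out were 800 to 1076 for infection in untreated cells, 1880 to 4624 with ethanol, 951 to 3031 with EPA and 720 to 1038 with ceramide. They were 0 to 11 and 0 to 2 for ethanol against untreated in uninfected and infected cells, 27 to 100 and 29 to 54 for EPA against ethanol, 5 to 30 and 22 to 51 for ceramide against ethanol, and 2 to 7 and 1 to 4 for EPA against ceramide. For the interactions they were 18 to 43 with EPA, 26 to 102 with ceramide, 0 to 1 between EPA and ceramide and 0 to 1 with ethanol. With array weights (0.25 to 7.45) infection gave 3963 probes in untreated, 10928 in EPA and 3393 in ceramide treated cells. Ethanol against untreated then gave 36 and 1, EPA against ethanol 3227 and 516, ceramide against ethanol 303 and 59, EPA against ceramide 4028 and 118, and the interactions 1229 with EPA, 114 with ceramide, 118 between them and 1 with ethanol. With only the groups compared, infection gave 230 with ethanol, 200 with EPA and 602 with ceramide. EPA against ethanol then gave 0 and 0, ceramide against ethanol 0 and 8, EPA against ceramide 0 and 0 and the interactions with EPA and ceramide 9 and 15. Without the filter on dim probes infection gave 1596 with EPA and 966 with ceramide, ethanol against untreated 1 and 10, EPA against ethanol 49 in uninfected cells, EPA against ceramide 2 and 3, and the ceramide interaction 29. The floor of 32 gave 6 and 1 for ethanol against untreated. Ceramide against ethanol in uninfected cells gave 38 with that floor, 7 with median scaling, 32 with an offset of 50, 33 with the stricter filter (11 in infected cells), 28 with trend and robust and 21 without the 2 brightest arrays. EPA against ceramide gave 1 and 1 with median scaling, and in infected cells 15 with trend and robust and 1 without the 2 brightest arrays. The replicate block gave 1 for ethanol against untreated and 35 for ceramide against ethanol in uninfected cells and 4 for EPA against ceramide in infected cells, and moved no other count by over 1.5 times. The replicate numbers do not pair the samples in the labels. The deviations of 84 same-numbered pairs correlated at a median of 0.01088 (19 over 0.1), and 12 of 24 arrays correlated best with their own number. The highest same-number correlation was 0.5653, against 0.427 among other numbers, so some same-numbered arrays did deviate alike. List shifts numbered 54, and 18 with an estimated correlation, 56 with the replicate block, 64 with median scaling (42 of the 54 among them) and 47 with the mean over a gene's probes (44 of the 54). The cause was not tested for any of these moves. Normexp and a lot term were not run, the first because the values were background subtracted and the second because lots and groups coincide. Signal over background limits the folds given as "at least".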

Other observations

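The histone families in this part were picked, and their tests chosen, only after the result was seen, as 2 overlapping ones of 19 families looked at. Replication-dependent histone genes, whose messages are mostly made in S phase, rose with infection. Of 17 genes tested, 15 rose and 0 fell in the averaged comparison (median log2 difference 0.79, limma camera adjusted p = 8.85e-15; adjusted p = 0.00208 with an estimated correlation). H1f1 was above background on 12 of the 24 arrays, and in untreated cells, with 3 of 3 infected and 0 of 3 uninfected arrays above background, it rose at least 4.40-fold (adjusted p = 7.47e-06). In the averaged comparison H4bc24, above background on 23 arrays, was higher by 1.89, H2bc8 by 1.63 (adjusted p = 2.54e-14), H2ac8 by 1.42, H2ac6 by 1.24 and H2bc9 by 1.20. H2bc18 (0.14) and H2bc22 (0.18) did not pass.

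The rise was present in both lot steps. In untreated and ethanol treated cells 15 of 17 rose (median 0.96, adjusted p = 2.3e-18; adjusted p = 0.000621 with an estimated correlation), and in EPA and ceramide treated cells 12 of 17 (median 0.62, adjusted p = 1.96e-09; adjusted p = 0.0216 with an estimated correlation). Between EPA and ceramide 0 of 17 passed in limma. The cell cycle list did not pass in the averaged comparison, with 7 members higher and 9 lower of 45 (median -0.01, adjusted p = 0.85).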
